A study of Mus musculus with 2 samples.

How the data were processed

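The labels describe single-nucleus RNA sequencing of the prefrontal cortex of mice given METH or saline for 14 days, with 3 mice per group and 1 library per group. The labels' protocols name an iodixanol gradient, 10x 3′ chemistry and sequencing on an Illumina HiSeq instrument. The deposited values are whole-number UMI counts per gene and barcode. The submitters' processing notes name Cell Ranger 1.3.0 and Seurat 3.1.4 and the mm10 genome, while per the file headers the count matrix was written by software version 3.1.0. Neither the headers nor the labels state a filter on barcodes or genes, or an equalisation of depth between libraries. Barcodes end in 1 of 2 numbers, and 154 barcode sequences occur with both, so the numbers tell 2 libraries apart. No label or file ties a number to a group, and groups were not inferred from the values. The planned comparison of METH with Control per class, with its counts of genes and its list percentiles, was therefore not made, and the matrix was treated as 1 pooled sample with values for the whole and for each library.

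Of 20766 barcodes, those with at least 500 genes were kept, and doublets were called per library with Scrublet as run by Scanpy 1.11.5 (automatic thresholds of 0.110 in library 1 and 0.173 in library 2) and removed. UMIs per barcode ran from 431 to 67872, and the matrix held 66566100 UMIs on 24086 genes with at least 1 UMI. The planned maximum for mitochondrial UMIs removed no barcode, because no mitochondrial gene was found by symbol. For 145 cell type markers and the fixed lists, genes were matched by symbol, and 35 symbols occurred more than once in the matrix.

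For clustering, counts of each nucleus were scaled to 10000 and log-transformed, 3000 variable genes were chosen, scaled to a maximum of 10 and reduced to 50 principal components, and Leiden clusters at resolution 1 were made from 20 nearest neighbours (scikit-learn 1.9.0, umap-learn 0.5.12, igraph 0.11.9). Clusters without a name and with at least 60 nuclei were clustered a second time at resolution 0.5. A cluster received the name of the marker list with the highest mean level relative to the highest cluster. At least 3 markers had to reach 20 CPM and 25% of the highest cluster, the score had to be at least 1.5 times that of the next list with 3 detected markers, the 10 leading genes by fold (with 20 CPM added to both sides) were not to hold more markers of another class, and a cluster needed at least 30 nuclei. A cluster with a median UMI count under 33.3% of its library's and no own marker among its leading genes also stayed unnamed. Markers whose lowest cluster reached 10% of the highest were not used, which left 128 of 145. The first step gave 26 clusters, 6 of them unnamed, and the second gave 36, of which 12 were unnamed, with 9 classes named.

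The gene lists, cell type markers, filters, the rule for naming genes and the alternatives planned for them were chosen before the data were examined. The details of the naming rule, the second clustering, the removal of 4 haemoglobin genes and Ttr from variable genes and names, the number of principal components and neighbours, and the free RNA method were chosen after the data were seen. The graph setting was the one of 36 that left the fewest nuclei unnamed, and over these 36 the unnamed share ran from 5.18% to 14.7% and that of excitatory neurons from 37.0% to 43.8%.

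UMIs were summed per class and divided by the class total to give CPM, with exact Poisson 95% intervals, and shares have exact Clopper-Pearson intervals (SciPy 1.17.1, NumPy 2.4.6, pandas 2.3.3, Python 3.11.15). These intervals cover counting error only, since nuclei are not replicates, and no p-value was computed. The free RNA index of a class in each library was the CPM of Slc17a7. In excitatory neurons it was the summed CPM of a set of myelin genes times a ratio (0.185 in library 1 and 0.190 in library 2). That ratio was the CPM of Slc17a7 over that of these myelin genes. Both were summed over microglia, astrocytes, oligodendrocyte precursors, inhibitory neurons and striatal projection neurons. Within single classes of these it ran from 0.121 to 0.344 in library 1 and from 0.178 to 0.218 in library 2. The method assumes that free RNA has like proportions in all classes, which these ranges show to hold only roughly. The free RNA level of a gene was the index of the class times the lowest ratio of the gene's upper Poisson bound to the index over classes of at least 200000 UMIs. A gene was above free RNA in a class where the lower Poisson bound of its count exceeded that level. The level is an upper limit: for a gene that all classes make, its own expression counts as free RNA. A class with a high index, such as microglia, can then hardly exceed it. The highest class was taken among classes of at least 100 nuclei above free RNA, and was called clear where the exact conditional 95% interval of its ratio to the next class excluded 1. Among neuronal subclasses the same rules were used.

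From each list the text names up to 4 members with the highest CPM in any class and up to 2 with the highest ratio of the highest to the median class among members with at least 50 UMIs there, together with 10 genes named in advance (Drd1, Drd2, Fos, Arc, Bdnf, Gfap, Grin2a, Grin2b, Gria1 and Slc1a2). Some genes that the rule names are not reported here. Members that were named for having few UMIs or no level above free RNA, or for being markers, fall outside this rule and were chosen after their values were seen, as were the haemoglobin genes, Ttr, Malat1, Meg3, Miat and Snhg11. Shares of nuclei with a UMI were compared after drawing 500 UMIs without replacement from each nucleus, and no nucleus fell below that number. The procedure was tested on simulated counts for 200 genes placed in 1 class each over a free RNA background. Of the Poisson intervals 97.8% held the true level, 0.357% of classes without the gene were called above free RNA, and the true class was found for 100% of 67 genes at 40 CPM. The counts were drawn as Poisson with the same free RNA index, so these values were largely set by the design. Genes made by several classes, as many list members are, were not simulated.

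Alternatives covered the gene minimum, doublets, clustering resolution, seed and graph, centring of genes within libraries, the second clustering, the score ratio, the genes left out, per-nucleus means in place of summed counts, the free RNA classes, and the subtraction of the free RNA level from each CPM. The seed, the graph, the second clustering, the score ratio, the genes left out, the free RNA classes and the subtraction were added after the data were seen. Gene positions are those of the GENCODE annotation of mm10. Figures were drawn with Matplotlib 3.10.9.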

Results

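Single-nucleus RNA sequencing of the prefrontal cortex addressed how repeated methamphetamine (METH), a stimulant that raises synaptic dopamine, changes gene expression in each cell type of this region. Mice of the inbred C57BL/6 strain, male and 2 months old, received METH at 5 mg/kg or saline intraperitoneally over 14 days, and the tissue of 3 mice was used for each group, METH and Control. Nuclei were separated on an iodixanol density gradient and put into droplets, where each nucleus received a barcode and each captured molecule a unique molecular identifier (UMI). The values are UMI counts in a matrix of 31040 genes and 20766 barcodes from 2 libraries, which a number at the end of each barcode tells apart. No label ties either number to METH or Control, so the comparison of METH with Control was not made, and the libraries are called library 1 and library 2, each with its own value. The matrix was treated as 1 pooled sample without replicates, and all intervals cover counting error only.

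Library 1 held 31273163 UMIs on 9890 barcodes, and library 2 held 35292937 UMIs on 10876 barcodes. The median was 2876 UMIs per barcode in library 1 and 2977 in library 2. The labels state that about 8000 nuclei were loaded, fewer than the barcodes of either library. A minimum of 500 genes left 19551 barcodes (8892 and 10659 in libraries 1 and 2), and 1624 of these were removed as doublets (10.8% of library 1 and 6.19% of library 2). The 17927 nuclei kept (7928 and 9999) had a median of 2970 UMIs and 1761 genes.

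Excitatory neurons were the most frequent class, with 43.3% (7760 nuclei, 42.6 to 44.0%), followed by oligodendrocytes, the myelin-forming cells, with 17.1% (3060 nuclei, 16.5 to 17.6%) and inhibitory neurons with 17.0% (3056 nuclei, 16.5 to 17.6%), with exact binomial 95% intervals in parentheses. Striatal projection neurons, the medium spiny neurons of the basal ganglia, made up 7.82% (1402 nuclei, 7.43 to 8.22%). Over 36 graph settings of the clustering their share ran from 5.82% to 7.82%, with a median of 6.69%, so the share given is the highest of these. Fibroblasts were named in 19 of the 36. Of classes not named in the setting used, endothelial cells were named in 3, pericytes in 5 and perivascular macrophages in 4. Microglia, the resident immune cells, made up 4.90% (879 nuclei, 4.59 to 5.23%), oligodendrocyte precursors 1.97% (353 nuclei, 1.77 to 2.18%), astrocytes 1.71% (307 nuclei, 1.53 to 1.91%), differentiating oligodendrocytes 0.641% (115 nuclei, 0.530 to 0.770%) and fibroblasts 0.368% (66 nuclei, 0.285 to 0.468%). Clusters that no marker list named held 5.18% (929 nuclei, 4.86 to 5.52%). A class name stands for nuclei that were like that class by its fixed markers. The labels name the prefrontal cortex alone, while medium spiny neurons belong to the basal ganglia. The nuclei may therefore come in part from outside that cortex, and the shares are those of the tissue as taken. The share of inhibitory neurons was 17.0% in library 1 and 17.1% in library 2, while that of striatal projection neurons was 5.35% in library 1 and 9.78% in library 2, that of oligodendrocytes 20.5% in library 1 and 14.3% in library 2 and that of astrocytes 0.631% in library 1 and 2.57% in library 2. Excitatory neurons made up 45.7% in library 1 and 41.4% in library 2, and unnamed clusters 3.27% in library 1 and 6.70% in library 2. Median UMIs per nucleus ran from 693 in microglia and 811 in oligodendrocytes to 2823 in inhibitory and 4411.5 in excitatory neurons, and a gene minimum acts on such shares: at 1000 genes oligodendrocytes made up 1.03%, microglia 2.54%, oligodendrocyte precursors 0.625% and astrocytes 0.809%, and no cluster was named fibroblast. With doublets kept, 14.0% of nuclei were named excitatory neurons and 37.4% stayed unnamed.

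**Figure D1:**
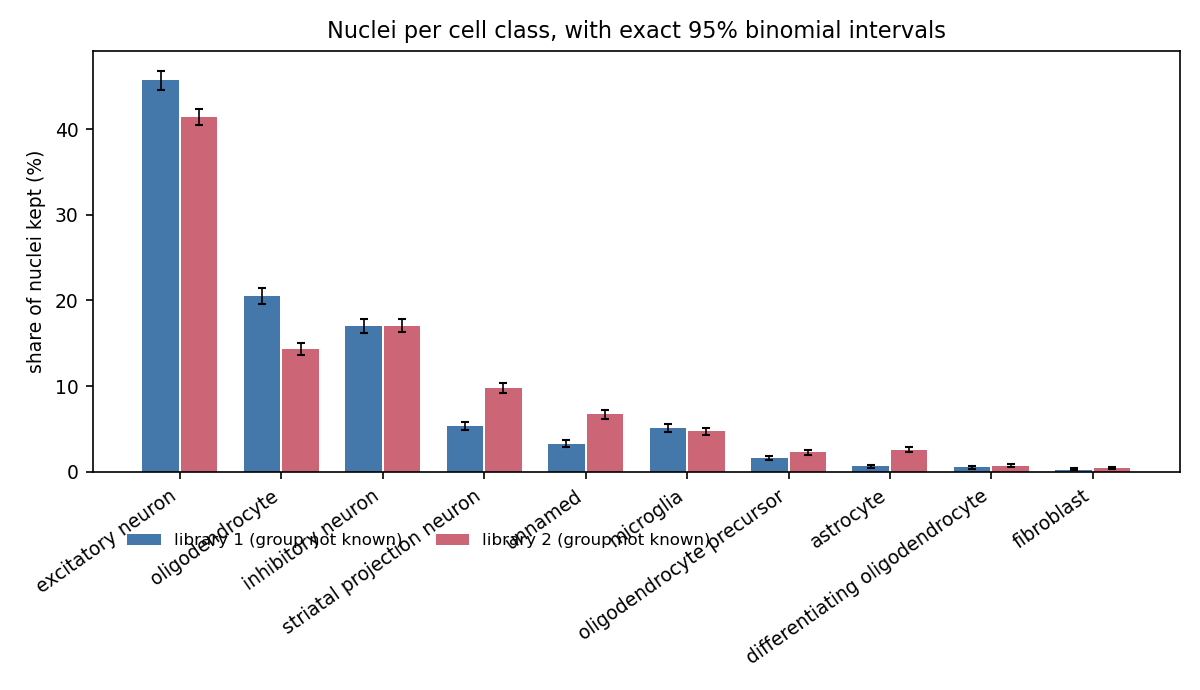
Share of the nuclei kept in each cell class (vertical axis, percent) for library 1 (blue) and library 2 (red), whose groups are not known. Bars stand for shares and lines for exact 95% binomial intervals. Astrocytes made up 0.631% in library 1 and 2.57% in library 2, and striatal projection neurons 5.35% in library 1 and 9.78% in library 2.

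Among excitatory neurons, 1619 nuclei carried the markers of layer 2/3, 1235 those of layer 6 corticothalamic neurons, 513 those of layer 5 extratelencephalic neurons, 332 those of layer 6b, 226 those of layer 5/6 near-projecting neurons and 174 those of the claustrum, a thin sheet of grey matter beside the cortex. Another 3661 excitatory nuclei received no subclass. The list for layer 6 intratelencephalic neurons kept too few usable markers to be scored. The claustrum name was therefore not weighed against these neurons, although Oprk1, a marker on their list, led the genes of the claustrum cluster. Inhibitory neurons divided into parvalbumin (871), somatostatin (840) and VIP (726) interneurons, and 619 had no subclass. No cluster was named for LAMP5 interneurons. The VIP cluster scored 0.812 for VIP and 0.672 for LAMP5, and a somatostatin cluster of 720 nuclei 0.438 and 0.387. Both were named because fewer than 3 LAMP5 markers were detected in them, so they may hold LAMP5 interneurons as well.

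For 20 gene lists fixed before the data were examined, UMIs were summed over the nuclei of each class and expressed as CPM, counts scaled to the same total in every class, with exact Poisson 95% intervals in parentheses. Of 314 listed genes, 301 were found by symbol and 273 had at least 50 UMIs over the named classes. Where a gene is said below to have fewer than 50 UMIs, unnamed clusters were likewise left out. In 8 classes of at least 100 nuclei, 265 of these lay above the level that free RNA (RNA of broken cells present in all droplets) could give in at least 1 class, and 8 in none. That level is an upper limit and includes expression shared by all classes. A gene not above it is therefore not shown to be absent, least of all in microglia, whose free RNA index was high. A total of 143 genes had a clear highest class, in that the exact interval of the ratio to the next class excluded 1, and 117 of these were neither naming markers nor among the 10 leading genes of a named cluster. The highest class was the same in both libraries for 137 of the 143. With the free RNA level subtracted from each CPM, an alternative chosen after the data were seen, 141 of the 143 kept their highest class. The interval lay above those of all other classes for 100, and in microglia for 9 of 29. That rule asks more than a clear highest class, which rests on the ratio to the next class. It was not counted without the subtraction, so how much of the fall from 143 to 100 is due to free RNA is not known. By list, the genes that stood apart in this way among those with a clear highest class were 2 of 7 in the immediate early genes, 8 of 10 in the dopamine system, 7 of 11 in the serotonin and adrenergic receptors, 10 of 12 in the ionotropic glutamate receptors, 9 of 9 in the metabotropic glutamate receptors and transporters, 14 of 15 in the GABA list, 12 of 13 in the neuropeptides and opioid receptors, 10 of 10 in vesicle release, 5 of 7 in the oxidative stress response, 0 of 4 in the unfolded protein response, 1 of 2 in astrocyte reactivity, 6 of 7 in microglial activation, 1 of 4 in the interferon response, 9 of 10 in myelin, 2 of 3 in the blood-brain barrier, 4 of 8 in the circadian clock, 0 of 2 in oxidative phosphorylation, 0 of 7 in the ribosomal proteins and 0 of 2 in the sex check. By class, 50 genes were highest in striatal projection neurons, 49 in excitatory neurons, 42 in inhibitory neurons, 42 in astrocytes, 41 in microglia, 18 in oligodendrocytes, 16 in oligodendrocyte precursors and 7 in differentiating oligodendrocytes. With at least 1000 genes per nucleus, 9 were highest in microglia, 30 in oligodendrocytes and none in the precursors or differentiating cells. Only classes of at least 100 nuclei could be the highest. With 1000 genes the precursors had fewer, so their count was fixed by that rule, and that of the differentiating cells may have been. With doublets kept 9 were highest in oligodendrocyte precursors.

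Immediate early genes, which neurons switch on within minutes of strong activity, reached their highest levels among neuronal subclasses in claustrum nuclei: 16 of the 23 members peaked there, and 10 of these stood clear of the next subclass. Fos, a transcription factor widely used as a marker of recent activity, had 64.5 CPM (49.0 to 83.4) in claustrum nuclei, 4.04-fold (2.99 to 5.38) the level of excitatory nuclei without a subclass. Bdnf, which encodes a growth factor of synapses, had 128 CPM (106 to 154) there, 4.34-fold (3.52 to 5.32) the next subclass, and Homer1, a postsynaptic scaffold gene, 516 CPM (470.3 to 565), or 1.43-fold (1.28 to 1.59). Arc, a regulator of synaptic strength, reached 90.1 CPM (71.6 to 112) and Junb 115 CPM (93.5 to 139). In each library these 5 genes were highest in claustrum nuclei, with Fos at 95.7 CPM in library 1 and 46.0 CPM in library 2 and Bdnf at 194 CPM in library 1 and 88.6 CPM in library 2. None of the list's genes served to name that cluster, although Nr4a2, of the same gene family as the members Nr4a1 and Nr4a3, was a naming marker.

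Across the 8 broad classes, 9 immediate early genes were highest in excitatory neurons, 5 in striatal projection neurons and 4 in microglia, and 7 had a clear highest class. After subtraction of the free RNA level 2 of these, Junb and Ier5 in microglia, had an interval above those of all other classes, while Arc, Homer1 and Dusp6 did not. Arc had 39.4 CPM (37.4 to 41.5) in excitatory neurons, 1.36-fold (1.09 to 1.72) the level of oligodendrocytes. Fos was at 14.1 CPM (12.9 to 15.4) in excitatory and 11.7 CPM (9.62 to 14.2) in inhibitory neurons, a ratio whose interval included 1. Bdnf was at 27.4 CPM (25.7 to 29.1) in excitatory neurons, also without a clear highest class. Microglia had the highest levels of Junb, with 143 CPM (115 to 175), of Ier5, with 105 CPM (81.5 to 133), and of Dusp6, a phosphatase that acts on the kinase ERK, with 86.6 CPM (65.6 to 112). Jund had 121 CPM (96.3 to 151) in microglia, not above the free RNA level of 116 CPM. Fosb was above free RNA in no class.

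Genes of dopamine signalling were concentrated in striatal projection neurons, where 8 of the 14 measured members were highest, all 8 clearly. Drd1 and Drd2, the dopamine D1 and D2 receptors, reached 139 CPM (128 to 151) and 83.9 CPM (75.0 to 93.5) there, but both belong to that class's naming markers, as do Ppp1r1b and Pde10a (1916 CPM, 1872 to 1959.6), a cyclic nucleotide phosphodiesterase, and Adcy5 (545 CPM, 522 to 569) was among its leading genes. Of the members that did not define the class, Gnal, the G protein that couples D1 receptors to adenylyl cyclase, had 585 CPM (561 to 609), 4.65-fold (4.33 to 4.99) the level of inhibitory neurons, and the receptor gene Drd3 had 41.3 CPM (35.2 to 48.2). Drd1 was at 11.4 CPM (10.3 to 12.5) in excitatory and 16.2 CPM (13.7 to 19.0) in inhibitory neurons, above free RNA levels of 6.86 and 10.8 CPM. It had 59.3 CPM (47.3 to 73.5) in layer 6b and 51.2 CPM (37.5 to 68.3) in claustrum nuclei. The inhibitory class includes nuclei without a subclass, so its value is not that of cortical interneurons alone. Nor need the values of striatal projection neurons be those of the prefrontal cortex. Drd2 was at 3.76 CPM (3.16 to 4.44) in excitatory neurons, narrowly above the free RNA level of 2.97 CPM. In inhibitory neurons it was at 6.08 CPM (4.6 to 7.90), not above that of 4.76 CPM. The excitatory level rests on the ratio of Slc17a7 to myelin genes, which ran from 0.121 to 0.344 over classes of library 1. The call for Drd2 in excitatory neurons is therefore not secure. Drd4, Drd5, Slc6a3 (the dopamine transporter) and Taar1 (a receptor that METH activates) had fewer than 50 UMIs, and the vesicular transporter gene Slc18a2 was above free RNA in no class.

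Receptors for serotonin and noradrenaline were divided among classes, with 6 of the 17 measured genes highest in striatal projection neurons, 5 in inhibitory neurons, 4 in excitatory neurons and 2 in microglia, 11 of them clearly. Adra1a was highest in inhibitory neurons (154 CPM, 146 to 162), and within these in VIP interneurons (304 CPM, 279 to 330.0). Htr2c had 272 CPM (256 to 289) in striatal projection neurons. Among subclasses of excitatory and inhibitory neurons it had 507 CPM (451 to 569) in near-projecting neurons, 1.59-fold (1.37 to 1.84) the next subclass. Htr4 showed the same pair, with 66.9 CPM (59.1 to 75.6) and 98.6 CPM (74.7 to 128). Htr1f was highest in excitatory neurons (229.7 CPM, 225 to 235), and in layer 6 corticothalamic nuclei it had 445 CPM (426 to 465).

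Every one of the 17 ionotropic glutamate receptor genes was measured, and 12 had a clear highest class. The NMDA receptor subunit Grin2a was highest in excitatory neurons with 774 CPM (765 to 783), 1.41-fold (1.37 to 1.45) the level of inhibitory neurons, and Grin2b in striatal projection neurons with 1251 CPM (1216 to 1286), 1.06-fold (1.03 to 1.1) that of excitatory neurons. Grin2c was an astrocyte transcript, with 379 CPM (321 to 445) there and 6.07 CPM in microglia, the next class. Among AMPA receptor subunits, Gria1 was highest in inhibitory neurons (967 CPM, 947 to 988), as was Gria4 (1332 CPM, 1308 to 1356), and Gria2 in excitatory neurons (2144 CPM, 2129 to 2159). The kainate receptor subunit Grik1 had 1008 CPM (988 to 1029) in inhibitory neurons and was among the leading genes of a somatostatin cluster. Grik2 was at 1629 CPM (1603 to 1655) in inhibitory and 1617 CPM (1577 to 1658) in striatal projection neurons, a ratio whose interval included 1.

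Resolved by subclass, 14 of the 17 genes had a clear highest neuronal subclass. Layer 2/3 nuclei led for Grin2b (1481 CPM, 1454 to 1508), 1.3-fold (1.27 to 1.33) the next subclass. Layer 5 extratelencephalic nuclei led for 5 genes, 4 of them clearly, among which Gria2 had 2936 CPM (2879 to 2994). Somatostatin interneurons were highest for Gria1 (1305 CPM, 1263 to 1349), VIP interneurons for Grik2 (2339 CPM, 2269.8 to 2409), and claustrum nuclei for Gria4 (2623 CPM, 2518 to 2731).

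Slc1a2, which encodes the main transporter that clears glutamate from synapses, was highest in astrocytes with 3133 CPM (2961 to 3313), 8.88-fold (7.48 to 10.6) the level of oligodendrocyte precursors. Slc1a3 had 2777 CPM (2615 to 2946) and is a naming marker of the class. Slc1a2 was also above free RNA in excitatory neurons, with 243 CPM (238 to 248) against 60.9 CPM. Of the 13 members, 4 were highest in astrocytes, 4 in excitatory neurons, 4 in striatal projection neurons and 1, also a glutamate transporter gene, in differentiating oligodendrocytes, and 9 stood clear, the last among them. The receptor Grm5 was highest in striatal projection neurons with 4062 CPM (3999 to 4126), 2.10-fold (2.06 to 2.15) the level of inhibitory neurons, and Grm7 with 2161 CPM (2115 to 2208). Among subclasses of excitatory and inhibitory neurons both were highest in near-projecting neurons, with 2969 CPM (2831 to 3113) and 2641 CPM (2509.8 to 2777).

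GABA receptor subunits separated by class, with 15 of 18 genes clearly highest in 1 class. Inhibitory and striatal projection neurons each led for 5 genes, astrocytes for 5 and excitatory neurons for 3. Gabrb1 was highest in astrocytes with 2021 CPM (1884 to 2167), 2.20-fold (2.05 to 2.36) the level of excitatory neurons, and so were the GABA transporter gene Slc6a11 (328 CPM, 274 to 390.1) and Gabrg1 (159 CPM, 122 to 204), which was also among the leading genes of an inhibitory cluster without a subclass. Striatal projection neurons had the highest Gabrg3 (1963 CPM, 1919.6 to 2008). Gabbr1 was at 528 CPM (459 to 605) in astrocytes and 455 CPM (431 to 481) in oligodendrocytes, and the interval of their ratio included 1. The synthesis genes Gad1 and Gad2 are naming markers of inhibitory neurons.

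Of 17 genes of neuropeptides and opioid receptors, 13 were clearly highest in 1 class, 7 in inhibitory neurons, 4 in striatal projection neurons, 1 in excitatory neurons and 1 in oligodendrocyte precursors, and 5 of these did not define a cluster. Oprk1, the kappa opioid receptor that dynorphin activates, had 89.0 CPM (79.9 to 98.9) in striatal projection neurons. In claustrum nuclei it reached 558 CPM (511 to 609), where it led the cluster's own genes. Oprk1 is also on the layer 6 intratelencephalic marker list, which was not scored. Oprd1, the delta opioid receptor, was highest in inhibitory neurons (59.9 CPM, 55.0 to 65.1), and there in parvalbumin interneurons with 119.8 CPM (108 to 133), 1.91-fold (1.59 to 2.31) the level of somatostatin interneurons. Sst (1989.6 CPM, 1961 to 2019) and Npy (1119 CPM, 1097 to 1140.4) peaked in inhibitory neurons and Penk, which encodes enkephalin, in striatal projection neurons (1067 CPM, 1035 to 1100.0), all 3 being genes that defined clusters. Cck had 1110.2 CPM (1031 to 1194) in microglia, not above the free RNA level of 1061 CPM, and 805 CPM (764 to 846) in VIP interneurons, against 441 CPM.

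Genes of synaptic vesicle release were highest in excitatory neurons for 10 of 16 members, 8 of them clearly. Syt1, the calcium sensor of release, had 3995 CPM (3974 to 4015), 1.35-fold (1.34 to 1.37) the level of inhibitory neurons. Snap25 had 1489 CPM (1477 to 1502), 1.53-fold (1.5 to 1.57), and Rims1, an active zone scaffold gene, 1485 CPM (1473 to 1498), 1.19-fold (1.17 to 1.21). Syn2 did not separate the classes, with 351 CPM (345 to 357) in excitatory and 350.4 CPM (338 to 363) in inhibitory neurons. Among subclasses Syt1 was highest in claustrum nuclei (5901 CPM, 5744 to 6062) and Rims1 in VIP interneurons (1931 CPM, 1868 to 1995).

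**Figure D2:**
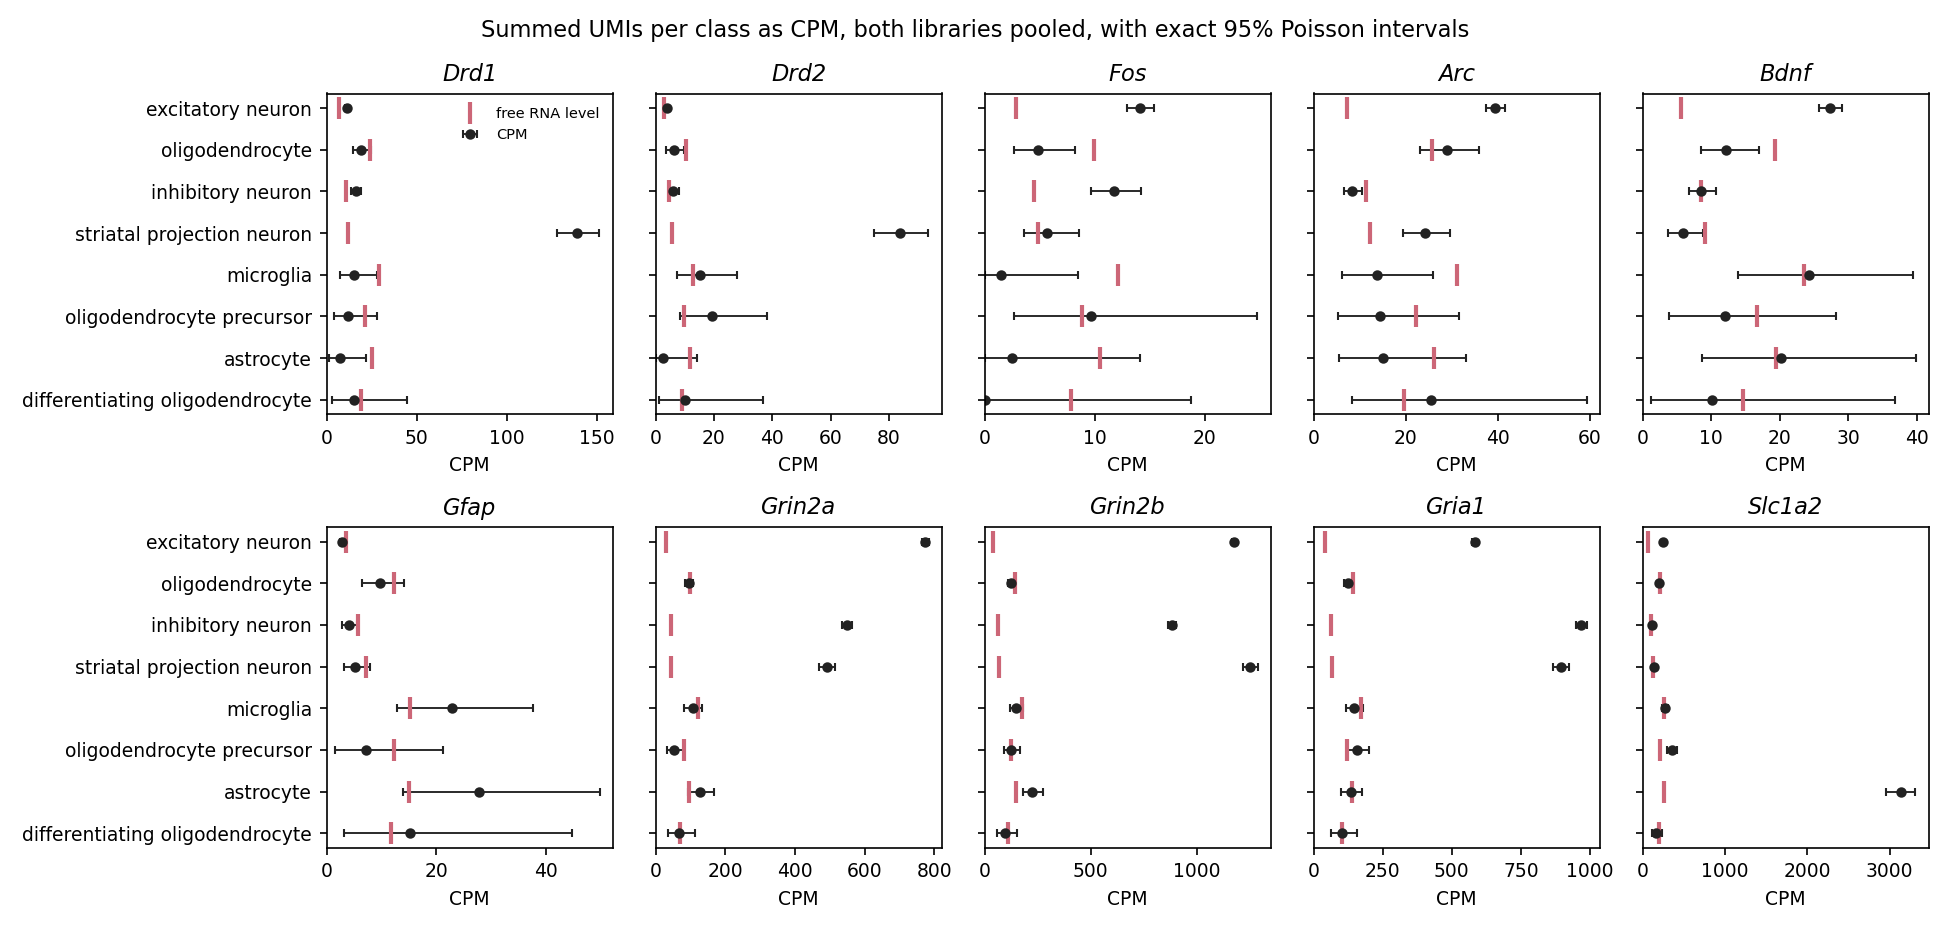
CPM of 10 genes (horizontal axis of each panel) in the 8 classes of at least 100 nuclei, both libraries pooled. Points stand for summed UMIs as CPM, lines for exact 95% Poisson intervals and red bars for the free RNA level. Drd1 and Drd2 stand out in striatal projection neurons (139 and 83.9 CPM) and Slc1a2 in astrocytes (3133 CPM), and the intervals of Gfap reach the free RNA level in all 8 classes.

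Antioxidant genes were led by astrocytes, which had the highest level of 8 of the 18 measured members, 6 of them clearly. Slc7a11, the cystine transporter that supplies glutathione synthesis, had 328 CPM (274 to 390.1) in astrocytes, 24.0-fold (12.3 to 53.7) the level of microglia. The metallothionein genes Mt1, Mt2 and Mt3 had 1589 CPM (1468 to 1719), 829 CPM (742 to 924) and 1286 CPM (1177 to 1403), and Prdx6 356 CPM (299.9 to 420.2). In neurons Slc7a11 was highest in claustrum nuclei with 50.1 CPM (36.5 to 67.0), 4.26-fold (2.68 to 6.83) the level of parvalbumin interneurons. Hmox1 had fewer than 50 UMIs, and Nqo1 was above free RNA in no class.

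Of the 14 measured genes of the unfolded protein and heat shock response, 13 were above free RNA in a class. Among classes above free RNA, 4 were highest in microglia, 3 in inhibitory neurons, 2 in oligodendrocytes and 1 in each of 4 other classes, and only those in microglia stood clear. The chaperone gene Hsp90b1 had 451 CPM (401 to 505) there, 1.76-fold (1.41 to 2.22) the next class, Hspa5, the main chaperone of the endoplasmic reticulum, 331 CPM (289 to 378), Xbp1, a transcription factor of the unfolded protein response, 156 CPM (128 to 189.7), and Sdf2l1 88.1 CPM (66.9 to 114). With the free RNA level subtracted these 4 genes were still highest in microglia, but none had an interval above those of all other classes. The cytosolic chaperone genes Hspa8 and Hsp90ab1 had 585 CPM (528 to 646) and 348 CPM (304 to 396) in microglia, not above free RNA levels of 625 and 357 CPM. For genes that all classes make, this outcome is largely set by how the level is built. The heat shock gene Hspa1a was above free RNA in no class, and Hspa1b and Hspb1 had fewer than 50 UMIs.

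Of the 8 measured genes of reactive astrocytes, 5 were above free RNA in a class and 2 had a clear highest class. Gfap, the classical reactivity marker and a naming marker of astrocytes, had 27.8 CPM (13.9 to 49.7) in that class. Its interval reached the free RNA level of 15 CPM, and Gfap was told apart from free RNA in no class. Only 10 of 307 astrocyte nuclei had a Gfap UMI, so absence of expression is not shown. Vim and Serpina3n were above free RNA in no class either, and 5 of the 13 members had fewer than 50 UMIs. The complement gene C4b was the list's member clearly highest in astrocytes, with 75.8 CPM (51.1 to 108) and 3.84-fold (1.94 to 8.02) the level of microglia. Stat3 was highest in microglia (143 CPM, 115 to 175), and S100a6 had 55.6 CPM (35.2 to 83.4) in oligodendrocyte precursors and 53.1 CPM in astrocytes, a ratio whose interval included 1.

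Microglial activation genes were highest in microglia for 5 of 9 measured members and in astrocytes for 3. Trem2, a lipid-sensing receptor of microglia, had 1251 CPM (1167 to 1339.8), 18.9-fold (11 to 35.7) the next class. Its adaptor gene Tyrobp had 702 CPM (639 to 769) and the lysosomal gene Cd68 439 CPM (389.8 to 493). In microglia Trem2 was at 1590.3 CPM in library 1 and 989 CPM in library 2, Tyrobp at 873 CPM in library 1 and 569 CPM in library 2 and Cd68 at 578 CPM in library 1 and 331 CPM in library 2. Apoe, the main lipid carrier of the brain, was highest in astrocytes with 11151 CPM (10824 to 11485), 2.49-fold (2.36 to 2.63) the level of oligodendrocyte precursors. The cytokine genes Il1b and Tnf and 4 further members had fewer than 50 UMIs.

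Interferon response genes were highest in microglia for 9 of 12 measured members, 3 of them clearly, of which 1, Bst2, stood apart from all other classes once the free RNA level was subtracted. Bst2, which tethers virus particles to the cell surface, had 103 CPM (80.2 to 131) in microglia, 3.38-fold (1.48 to 9.54) the next class. Rtp4 had 75.9 CPM (56.4 to 100.1), with a ratio to the next class whose interval included 1, and in microglia it was at 118 CPM in library 1 and 43.1 CPM in library 2. Ifi27 was highest in differentiating oligodendrocytes (575 CPM, 474 to 692), 1.29-fold (1.01 to 1.64) the level of the precursors, but did not stand apart after that subtraction.

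Myelin genes were oligodendrocytic in 11 of 12 cases, 10 of them clearly, but 6 of the list are naming markers of that class, among them Mbp, Mag and Cldn11. Mbp had 3948 CPM (3876 to 4021), Mag 1935 CPM (1884 to 1987) and Cldn11 1786 CPM (1737 to 1835). Aspa, which releases acetate for myelin lipid synthesis, had 778 CPM (746 to 811) and was among the leading genes of an oligodendrocyte cluster. Ugt8a, which makes the myelin lipid galactosylceramide, had 756 CPM (724 to 788) in oligodendrocytes and 733 CPM (618 to 863) in differentiating oligodendrocytes, and the interval of their ratio included 1.

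No cluster was named endothelial in the setting used, while 3 of the 36 graph settings named one. The endothelial genes Cldn5, Abcb1a, Cdh5 and Slco1a4 had fewer than 50 UMIs over the named classes. These leave out an unnamed cluster of 36 nuclei with Slco1a4 and Cldn5 among its leading genes. In their highest cluster of the first step Cldn5 had 168 CPM and Slco1a4 204 CPM. Of the 8 measured members of the blood-brain barrier list, 3 had a clear highest class. The tight junction gene Tjp1 was highest in differentiating oligodendrocytes (489 CPM, 396 to 597). Mfsd2a, a lipid transporter gene, had 162 CPM (125 to 206) in oligodendrocyte precursors and 132 CPM (86.4 to 194) in differentiating oligodendrocytes, and Abcg2 had 92.6 CPM (70.9 to 119) in microglia and 91.8 CPM (65.0 to 126) in oligodendrocyte precursors, both with ratios whose intervals included 1.

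Circadian clock genes were highest in astrocytes for 7 of 14 measured members, 5 of them clearly, and 2 of these, Dbp among them, stood apart from all other classes once the free RNA level was subtracted. Dbp, a transcription factor at the output of the clock, had 316 CPM (263 to 376) in astrocytes, 2.18-fold (1.78 to 2.65) the level of striatal projection neurons. Npas2, the partner of the core clock protein in forebrain neurons, was highest in striatal projection neurons with 209 CPM (195 to 224), 1.56-fold (1.44 to 1.68) the level of excitatory neurons. Clock (187 CPM, 171 to 203) in oligodendrocytes did not separate from the next class. Tef had its highest CPM in astrocytes (159 CPM), where it was not above the free RNA level of 128 CPM. Among classes above free RNA it was highest in oligodendrocytes (153 CPM, 139 to 168), without a clear highest class. Per3 had no UMI in the matrix.

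Among neuronal subclasses 15 of the 21 measured nuclear genes of oxidative phosphorylation were highest in parvalbumin interneurons, fast-firing cells, but only 2 of these stood clear of the next subclass, and no member did in another subclass. Across broad classes 2 members had a clear highest class, in both cases astrocytes. The genes named next were chosen by their level and not for being these 2. Cox8a had 940.0 CPM (847 to 1041) in astrocytes and Atp5b 422 CPM (360.4 to 491), with 244 CPM (226 to 262) in parvalbumin interneurons, and in astrocytes Cox8a was at 329.7 CPM in library 1 and 1050.5 CPM in library 2. Free RNA levels in astrocytes were 779 CPM for Cox8a and 296 CPM for Atp5b, and with these subtracted 161 CPM (68.0 to 262) and 126 CPM (64.3 to 195) remained. After that subtraction 1 of the 2 members with a clear highest class kept it, and none had an interval above those of all other classes. Cox6a1 (547 CPM, 492 to 606), Ndufa4 (507 CPM, 454 to 565), Cox7a2 (320.4 CPM, 279 to 367) and Ndufa2 (273 CPM, 235 to 316) had their highest CPM in microglia, where none of them was above free RNA. In excitatory neurons the whole list came to 1305 CPM in library 1 and 2317 CPM in library 2. Free RNA differed between the libraries as well, with Slc17a7, a transcript of excitatory neurons, at 105 CPM in the inhibitory neurons of library 1 and 202 CPM in those of library 2.

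Among classes above free RNA, and by CPM with free RNA included, 10 of 17 measured ribosomal protein genes were highest in microglia, 7 of them clearly. Rpl41 had 977 CPM (902 to 1055), Rplp1 504 CPM (451 to 561), Rps27a 263 CPM (225 to 305), Rpl32 241 CPM (205 to 282) and Rpl4 241 CPM (205 to 282), against free RNA levels of 854, 360.3, 204, 182 and 192 CPM. Rpl19, at 273 CPM (235 to 316) in microglia, was not above free RNA there. With the free RNA level subtracted, 6 of the 7 were still highest in microglia, Rpl41 was higher in oligodendrocyte precursors (189.7 CPM) than in microglia (122 CPM), and none had an interval above those of all other classes. In excitatory neurons the list came to 627 CPM in library 1 and 1321 CPM in library 2. None of the 11 mitochondrially encoded transcripts of the RNA quality list was found in the matrix by symbol.

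Of the 5 measured members of the sex check list, 2 had a clear highest class, in both cases striatal projection neurons. Among genes of the Y chromosome Eif2s3y had 334 CPM (279 to 396) in astrocytes, Uty 239 CPM (176 to 318) and Ddx3y 219 CPM (158 to 295) in differentiating oligodendrocytes, and Kdm5d 75.1 CPM (66.8 to 84.3) in striatal projection neurons, 1.16-fold (1.01 to 1.34) the level of inhibitory neurons. The highest class exceeded the median class 1.42-fold for Eif2s3y, 1.48-fold for Uty and 1.34-fold for Kdm5d. Xist, the RNA that silences an X chromosome in females, had 46 UMIs over all named classes, and the labels give male animals.

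The share of nuclei with a UMI was compared at equal depth for the 10 genes singled out in advance, by drawing 500 UMIs from each nucleus, which all kept nuclei had. Exact binomial 95% intervals follow each thinned share. Drd1 was seen in 6.49% (5.26 to 7.91%) of striatal projection neurons and 0.882% (0.582 to 1.28%) of oligodendrocytes, which serve as a class without the gene, and before thinning in 27.5% and 1.67%, at medians of 2707.5 and 811 UMIs. Drd2 was seen in 3.64% (2.72 to 4.76%) and 0.294% (0.135 to 0.558%) of the same classes (17.6% and 0.556% before thinning). In excitatory neurons Drd1 and Drd2 were seen in 0.580% (0.423 to 0.775%) and 0.232% (0.138 to 0.366%) (4.87% and 1.74% before thinning), at or below the oligodendrocyte share. Free RNA is a larger part of oligodendrocyte than of excitatory UMIs, with indices of 222 and 71.7 CPM in library 1 and 496 and 128 CPM in library 2. These shares therefore do not tell whether excitatory neurons express the genes. Their CPM there lay above the free RNA level, for Drd2 only narrowly.

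Grin2a was seen in 29.4% (28.4 to 30.5%) of excitatory neurons and 4.12% (3.44 to 4.88%) of oligodendrocytes (88.6% and 7.75% before thinning, at medians of 4411.5 and 811 UMIs). Grin2b was seen in 43.2% (40.6 to 45.9%) of striatal projection neurons, 43.5% (42.4 to 44.6%) of excitatory neurons and 5.56% (4.77 to 6.43%) of oligodendrocytes (91.1%, 96.3% and 9.71%). Gria1 was seen in 33.8% (32.1 to 35.5%) of inhibitory neurons, 35.1% (32.6 to 37.7%) of striatal projection neurons and 5.59% (4.80 to 6.46%) of oligodendrocytes (77.6%, 83.9% and 9.97%). For both genes the class highest by CPM did not have the highest thinned share, and its interval overlaps that of the class that did. Slc1a2 was seen in 77.5% (72.4 to 82.1%) of astrocytes, with a median of 1192 UMIs, and 9.44% (8.43 to 10.5%) of oligodendrocytes (96.1% and 15.8%). Fos was seen in 0.657% (0.490 to 0.863%) of excitatory neurons and 0.261% (0.113 to 0.514%) of oligodendrocytes (4.70% and 0.458%), Bdnf in 1.40% (1.15 to 1.69%) and 0.458% (0.25 to 0.766%) (9.56% and 1.14%), and Arc in 1.80% (1.52 to 2.13%) and 1.18% (0.825 to 1.63%) (13.7% and 2.61%). Gfap was seen in 1.3% (0.356 to 3.30%) of astrocytes and 0.458% (0.25 to 0.766%) of oligodendrocytes (3.26% and 0.882%). For Fos, Arc and Gfap the interval overlaps that of oligodendrocytes.

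In the mm10 (GRCm38) assembly and its GENCODE annotation, these 10 protein-coding genes lie at the following positions. Drd1 (ENSMUSG00000021478) spans chromosome 13, 54051183 to 54055705, minus strand. Drd2 (ENSMUSG00000032259) spans chromosome 9, 49340627 to 49408177, plus strand. Fos (ENSMUSG00000021250) spans chromosome 12, 85473890 to 85477273, plus strand. Arc (ENSMUSG00000022602) spans chromosome 15, 74669083 to 74672570, minus strand. Bdnf (ENSMUSG00000048482) spans chromosome 2, 109674700 to 109727007, plus strand. Gfap (ENSMUSG00000020932) spans chromosome 11, 102887336 to 102900912, minus strand. Grin2a (ENSMUSG00000059003) spans chromosome 16, 9567898 to 9995560, minus strand. Grin2b (ENSMUSG00000030209) spans chromosome 6, 135713233 to 136173511, minus strand. Gria1 (ENSMUSG00000020524) spans chromosome 11, 57011387 to 57330244, plus strand. Slc1a2 (ENSMUSG00000005089) spans chromosome 2, 102658659 to 102790784, plus strand.

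Haemoglobin transcripts, which belong to red blood cells, were found in all classes. The summed CPM of Hba-a1, Hba-a2, Hbb-bs and Hbb-bt was 442 CPM (368 to 526) in microglia of library 1 and 1275 CPM (1162 to 1395) in those of library 2, and 260.1 CPM (235 to 287) and 999 CPM (947 to 1053) in oligodendrocytes. In layer 6 corticothalamic nuclei it was 73.5 CPM (62.9 to 85.4) in library 1 and 1639.9 CPM (1588 to 1693) in library 2, where 1 nucleus held 3047 of 3763 haemoglobin UMIs, and without it the level was 313 CPM (290.4 to 337). Parvalbumin interneurons had 88.6 CPM (73.7 to 106) in library 1 and 1130.0 CPM (1078 to 1184) in library 2, and without 1 nucleus with 963 of 1772 such UMIs 518 CPM (483 to 554). In microglia and oligodendrocytes no nucleus held more than 7. Ttr, an abundant transcript of the choroid plexus, was at 5.4 CPM (2.33 to 10.6) in oligodendrocytes of library 1 and 109 CPM (92.7 to 128) in those of library 2. These 5 genes were left out of the clustering.

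**Figure D3:**
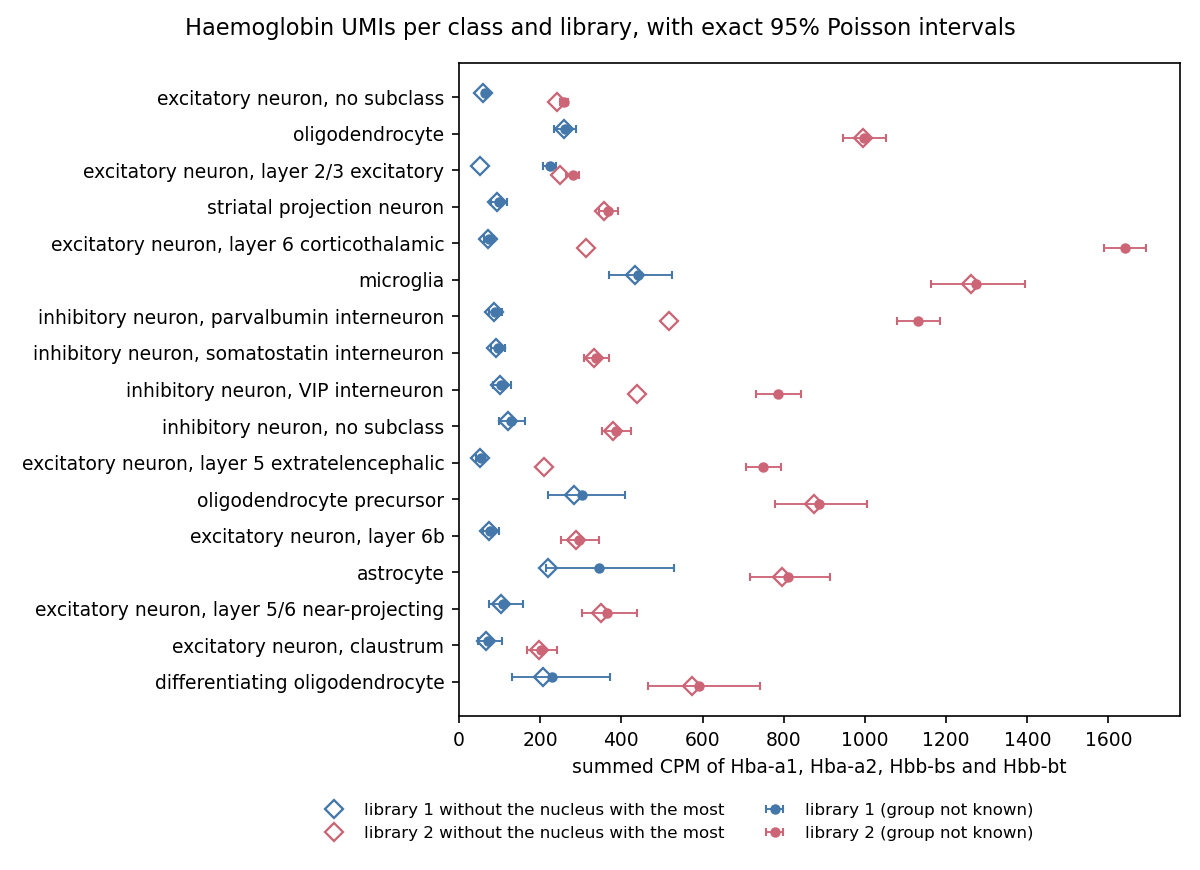
Summed CPM of 4 haemoglobin genes (horizontal axis) per cell class or neuronal subclass for library 1 (blue) and library 2 (red), whose groups are not known. Points stand for summed UMIs as CPM and lines for exact 95% Poisson intervals. Open diamonds stand for CPM without the 1 nucleus that has the most haemoglobin UMIs. In layer 6 corticothalamic nuclei of library 2 that nucleus held 3047 UMIs, and the level was 1639.9 CPM (1588 to 1693) with it and 313 CPM (290.4 to 337) without it.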

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

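The alternatives named here as added, and the values for claustrum nuclei, were chosen after the data were seen. A minimum of 1000 genes kept 13591 nuclei and gave, by class, excitatory neuron 56.9%, oligodendrocyte 1.03%, inhibitory neuron 21.5%, striatal projection neuron 8.48%, unnamed nuclei 7.53%, microglia 2.54%, oligodendrocyte precursor 0.625% and astrocyte 0.809%, with fibroblasts at 0%. It favours classes with many UMIs by construction. Of list members, 30 were then highest in oligodendrocytes, 9 in microglia, 0 in oligodendrocyte precursors and 0 in differentiating oligodendrocytes. The precursors then had fewer than the 100 nuclei that a highest class needs, so their count was fixed by that rule. The count for differentiating oligodendrocytes may have been fixed in the same way. Members reported as highest in precursors therefore had to change class, which also lowers the agreement given below for 1000 genes. Keeping doublets gave excitatory neuron 14.0%, oligodendrocyte 15.7%, inhibitory neuron 16.0%, striatal projection neuron 6.92%, unnamed nuclei 37.4%, microglia 4.54% and astrocyte 1.94%, with 9 list members highest in oligodendrocyte precursors. In that setting 19 clusters with 6053 nuclei that scored highest as excitatory neurons stayed unnamed for too few detected markers.

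Leiden resolution 0.5 gave excitatory neuron 44.3%, unnamed nuclei 4.03%, microglia 5.48% and differentiating oligodendrocyte 0.485%, and resolution 2 gave inhibitory neuron 15.9%, striatal projection neuron 8.38% and unnamed nuclei 5.92%. Centring genes within each library gave inhibitory neuron 16.3%, striatal projection neuron 6.64%, unnamed nuclei 6.53% and microglia 5.65%. Of the added alternatives, leaving out the second clustering gave inhibitory neuron 13.6% and unnamed nuclei 9.0%, with fibroblasts at 0%, and keeping the haemoglobin genes and Ttr among the variable genes gave striatal projection neuron 6.86%, unnamed nuclei 6.26% and differentiating oligodendrocyte 0.524%. Another seed gave striatal projection neuron 6.72%, unnamed nuclei 5.61% and microglia 5.48%, and 40 components with 15 neighbours and a second resolution of 0.3 gave excitatory neuron 41.2%, inhibitory neuron 16.0%, striatal projection neuron 6.69%, unnamed nuclei 9.27% and fibroblast 0.234%. For the settings in this paragraph the cause was not tested.

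In the settings above, shares of the 9 reported classes and of unnamed nuclei that are not given stayed within their intervals. A lower score ratio, added later, moved no share. Classes absent from the reported analysis were not compared, and the setting with 40 components, 15 neighbours and a second resolution of 0.3 named 10 classes. Counts of members were computed only with 1000 genes, doublets kept, per-nucleus means, mitochondrial genes left out of the total, 40 components and both free RNA alternatives, and those not named stayed within 1.5 times. With a minimum of 200 genes only the 19185 nuclei kept and the astrocyte share were compared, and clusters that scored highest as fibroblast stayed unnamed. Over the 36 graph settings differentiating oligodendrocytes were named in 35. The settings for mitochondrial UMIs could move nothing, since no such gene was found. The highest class was the same for 165 of 270 list members with 1000 genes, 224 of 268 with doublets kept, 262 of 273 with per-nucleus means, and, among added alternatives, 261 of 273 with free RNA taken from fewer and larger classes, 239 of 273 with the free RNA level subtracted and 258 of 272 with 40 components. Values of single genes were counted together with the share of claustrum nuclei, except with per-nucleus means, where that share was not computed. Of these values 59 moved beyond their intervals and 48 did not with 1000 genes, the claustrum share being among those that moved. With doublets kept 40 moved and 67 did not, with per-nucleus means 20 and 82, and with 40 components 6 and 101. Subtracting the free RNA level lowers such values by construction, so only highest classes were compared there.

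In claustrum nuclei Fos ran from 63.5 to 64.0 CPM, Arc from 88.9 to 90.9 CPM, Bdnf from 127 to 129 CPM and Homer1 from 513 to 528 CPM over 1000 genes, doublets kept and 40 components, all within the intervals of the reported values, and the share of claustrum nuclei was 1.33% with 1000 genes.

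No paired analysis was possible because each group has 1 library and the libraries are not mapped to groups. For the same reason the alternatives planned for METH against Control were not run: other scalings (ratios centred on the median gene), per-nucleus means, thinned UMIs, doublets kept and the gene minimum, other CPM and ratio limits for counted genes, and another UMI minimum for list members. Depth limits what can be said of microglia and oligodendrocytes, with medians of 693 and 811 UMIs per nucleus.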

Other observations

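Of the tests reported here, that of the haemoglobin UMIs in 1 nucleus, that of the astrocyte markers without the free RNA index and that of the other nuclear RNAs over Malat1 were chosen after the result was seen. Several unnamed clusters carried genes of recognisable cell kinds. One cluster led by Slc5a7, Chat and Lhx8, genes of neurons that make acetylcholine, held 59 nuclei, 21 in library 1 and 38 in library 2. Another, led by Top2a, a gene of dividing cells, and Igfbpl1, a gene of young neurons, held 178 nuclei, 43 in library 1 and 135 in library 2, while those led by Ntng1 and Fyb2 held 232 nuclei, 108 in library 1 and 124 in library 2, and 13 nuclei, 0 in library 1 and 13 in library 2. The cluster led by Ccl5 and Cd74, genes of lymphocytes and antigen presentation, held 43 nuclei, 18 in library 1 and 25 in library 2, another led by Cd74 with Ccl5 among its genes held 27 nuclei, 10 in library 1 and 17 in library 2, and that led by Ly6c1, Cldn5, Rgs5 and Acta2, genes of blood vessel walls, held 36 nuclei, 7 in library 1 and 29 in library 2. The cluster led by Ttr, haemoglobin genes and Vtn held 159 nuclei, 14 in library 1 and 145 in library 2.

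In layer 6 corticothalamic nuclei of library 2 the haemoglobin genes had 1639.9 CPM (1588 to 1693), against 280.2 CPM (265 to 297) in layer 2/3 nuclei. Free RNA was taken to reach all nuclei in like proportions. Under that assumption it is argued against as the source of most of these UMIs. In the layer 6 corticothalamic nuclei, 1 nucleus held 81.0% (79.7 to 82.2%) of the haemoglobin UMIs and 0.161% of the other UMIs. A candidate explanation is red blood cells caught in the droplet of that nucleus: the 1% with the most haemoglobin, 12 nuclei, all of library 2, held 79.6% of these UMIs in both libraries together, most of them in that 1 nucleus. Without it the level of library 2 was 1.12 times (1.02 to 1.23) that of layer 2/3. Per UMI of the myelin genes it was 0.851 times (0.763 to 0.949). In library 1 the latter ratio was 0.297 (0.247 to 0.357), so the assumption of like proportions is not secure. No biological explanation was tested, since the libraries are not mapped to groups.

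Astrocytes had a share in library 2 that was 4.08 times that in library 1 (3.0 to 5.63). Loss of low-UMI astrocytes to the gene minimum is argued against, because with a minimum of 200 genes the ratio kept a lower 95% bound of 2.93. Astrocytes may instead have been alike in the tissue of both libraries and lost as nuclei from library 1. In 3 other classes, 6 astrocyte markers per UMI of the free RNA index differed 1.31-fold (1.22 to 1.41). That is less than the share of astrocytes did, but the interval excludes 1. Without division by that index, which was itself higher in library 2, their summed CPM was 51.0 in library 1 and 123 in library 2, 2.41-fold (2.24 to 2.60), so this explanation rests on the index. Shares of other classes differed as well, with striatal projection neurons at 5.35% in library 1 and 9.78% in library 2, and oligodendrocytes at 20.5% and 14.3%. A difference in the tissue taken, between animals or between groups stays open. No biological explanation was tested because the libraries are not mapped.

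Malat1, an RNA kept in the nucleus, was at 46164 CPM in excitatory neurons of library 1 and 29156 CPM in those of library 2, a ratio of 0.632, while the ribosomal list was 2.11 times as high in library 2. Dilution by cytoplasmic RNA as the whole cause is argued against: Meg3, Miat and Snhg11, other long nuclear RNAs, would fall as far, but their ratio over that of Malat1 was 1.36 (1.35 to 1.37). As a part of the cause it may remain, since the 3 RNAs had a ratio of 0.859, between the bounds of 0.8 and 0.9 set for the test. No biological explanation was tested, since neither library is tied to a group.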
